A study of Mus musculus with 2 samples.

How the data were processed

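The data are ATAC-seq peak lists from the stomach of newborn mice, from 2 biological replicates that form 1 group. The authors deposited 12 lists in the narrowPeak layout on build mm10. For each replicate there is a list of ranked peaks of the comparison by irreproducible discovery rate (IDR), a list that passed its threshold, and a less strict list of peaks found in both pseudoreplicates of the same reads. For both replicates combined there are a conservative thresholded list, an optimal thresholded list, a replicated list, a pseudoreplicated list and 2 ranked lists. The aligner, the peak caller, their versions and settings, and the read depth are not given in the sources used here. The sources list a further parent file for some combined lists without saying what it holds.

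Each peak has a deposited score from 0 to 1000, which the authors took from the IDR value in the ranked and thresholded lists and from the peak caller in the others. The lowest score in the thresholded lists was 540, which corresponds to an IDR of 0.05. The signal of each peak is the narrowPeak signal value as deposited by the authors, and what it is relative to is not stated. The significance of each peak is deposited as the -log10 of its p-value from the authors' caller, and the ranked lists hold the -log10 of the global IDR value. The position of the summit is deposited in bases from the start of the peak. No value was normalised again. The main measure is whether a region is listed, the signal values serve to rank regions, and the -log10 values entered no result. Because only listed peaks are deposited, a region that is not listed is not shown to be closed.

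The 2 replicates were treated as a single group, taken from the labels. Peaks that overlapped were merged into regions, with the summit and signal of the peak of highest signal. The main catalogue was the conservative thresholded list, because it alone uses the difference between replicates in its threshold. All lists were checked against the chromosome lengths of the build, and 0 chromosomes had a peak past the end. Peaks on unplaced sequences and on the mitochondrial genome were left out of the regions.

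Gene models were those of GENCODE mouse release 21, with 41406 annotated starts of 21827 protein-coding genes. A promoter region has its summit within 1000 bases of a start, and a distal region lies over 1000 bases from each start of a protein-coding gene. Locations were compared with 100 random placements on the same chromosome by bedtools shuffle. A gene counted as accessible where a region overlapped the window of 1000 bases on either side of a start. Regions were not assigned to a single gene, so a region could count for neighbouring genes as well. Each of 24 gene lists (360 entries, all matched, 1 of them through an older symbol) was tested against all protein-coding genes. The promoter test was a two-sided exact test within 10 deciles of the observed to expected CpG ratio of the promoter, since CpG-rich promoters are open in most tissues. Of the genes in the lowest decile 2.43% were accessible, and of those in the highest 94.2%. The distal test compared the mean number of distal regions within 50000 bases of a start with 100000 random lists of the same size, matched on deciles of the number of genes within 100000 bases. The number and spread of the starts of a gene were not matched. Adjusted p-values follow Benjamini and Hochberg over the 24 lists or the 30 consensus sequences of a class, with a threshold of 0.05. Hoxa5 is in 2 lists, the mesenchyme transcription factors and Hox paralogs 1 to 5.

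Each consensus was matched exactly on both strands in a window of 101 bases at the summit and in a window of the same size 1000 bases away on a randomly drawn side, and the pairs were compared by a two-sided exact McNemar test. The FOXA and FOXF consensus sequences are reverse complements of each other and gave the same counts. Ratios have exact 95% intervals for counting error. For a consensus with 0 windows in the flank the ratio was set against a floor of 3 windows, here and among the alternatives. Ranks of signal were compared across regions by Spearman correlation without a p. A region found in 1 replicate only is in its thresholded list and overlaps nothing in the less strict list of the other.

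The named genes follow a rule. In each list these are the 3 members with the highest signal at the promoter and up to 2 members without a region, first in alphabetical order. Beyond the lists these are the 10 strongest regions at promoters and the 10 elsewhere, the 10 genes with the most distal regions, and the 5 strongest regions of each replicate alone. Of the consensus sequences these are the 6 with the largest and the 3 with the smallest ratio past the threshold. Names outside this rule are given as such.

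The alternatives were other lists, windows, overlap rules and strata, the regions of highest signal, either replicate alone, and ratios set against 20 permuted consensus sequences, with 0.5 added to both counts of these and of the consensus. The gene lists, consensus sequences, tests and alternatives were fixed before the data were examined, apart from the tests and alternatives named as later choices beside their results, the floor of 3 windows and the added 0.5. The steps were tested on simulated data. Of random lists, 3.70% passed an unadjusted threshold of 0.05 in the promoter test and 2.67% in the distal test, and 98% and 97% of lists with a planted excess passed. The simulated genes were independent of one another, so these rates do not cover lists whose neighbouring genes share regions. All planted CTCF sites were found (100%), 0 other consensus sequences were called, and the overlap counts differed from those of bedtools by 0. The simulated summit and flank windows had the same base composition, so the motif simulation does not cover windows that differ in GC content. Sequence similarity to the mitochondrial genome was found with blastn. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, bedtools 2.31.1 and blastn 2.17.0.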

Results

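Accessible chromatin was mapped in the stomach of mice on the day of birth by ATAC-seq, in which a transposase inserts sequencing adapters into DNA that is not wrapped in nucleosomes. The samples form 1 group of 2 biological replicates, and per the labels each is a pool of stomach tissue from male and female pups. The pool of replicate 1 came from 15 mice, and the labels give no number of mice for replicate 2. The deposited files hold lists of peaks and no reads or counts, so the depth of each library is unknown. The labels state no purpose beyond the assay itself, and the question addressed here is which promoters, distal regions and sequence motifs were accessible in this tissue. With 1 group and 2 samples no difference between animals could be tested, and no value has an error over animals. Each p-value compares genes or regions within a list of peaks. Signal values are those the authors gave for each peak, and what they are relative to is not stated in the sources used here. Coordinates are those of build mm10 (GRCm38), counted from 1.

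Regions at promoters had the higher median signal, and the 10 regions with the highest signal at promoters lay at 2610008E11Rik, Tmem218, Kifap3, Cldnd1, Zfp738, Exoc4, Zfp81, Depdc1a, Scfd1 and Hltf. Their signal values ran from 27.1 at 2610008E11Rik (chromosome 10, 79097130 to 79097915) to 24.1 at Hltf (chromosome 3, 20057409 to 20058359). Kifap3 encodes a subunit of the kinesin-2 motor, Exoc4 a subunit of the exocyst, and Scfd1 a protein of transport between endoplasmic reticulum and Golgi, while Zfp738 and Zfp81 encode zinc finger proteins. The 10 regions with the highest signal outside promoters had values from 59.4 to 31.0, and the nearest genes were Pak3, Abcb11, G6pd2, Gm5426, Frmd4a, Cdh20, Tyrp1, Myl12b, Cd209a and Hic2. The highest of them, 35531 bases from the nearest annotated start of Pak3, spans 143482934 to 143483181 of the X chromosome. Of these 10 regions, 4 (nearest genes Abcb11, G6pd2, Gm5426 and Tyrp1) match the mitochondrial genome in sequence.

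The main catalogue, the combined list that passed the conservative threshold between the replicates, holds 64590 peaks in 31649 separate regions. These cover 25.1 Mb, or 0.921% of the genome, with a median width of 744 bases. Of the regions, 11882 (37.5%) had their summit within 1000 bases of an annotated transcription start of a protein-coding gene, against 2.22% ± 0.0953 (SD of 100 random placements on the same chromosome), which is 16.9 times as many. Exons held 4.09% of the regions against 3.73%, introns 33.7% against 43.3%, and the space between genes 24.7% against 50.8%. The two-sided permutation p was 0.0198 for each of the 4 locations, the smallest that 100 placements can give. The median signal was 9.52 for regions at promoters, 5.50 in exons, 5.68 in introns and 5.96 between genes. The share in exons depended on the list. It was 2.65% for the 15824 regions of highest signal, below the random share, and by the permutation test it did not differ from that share with a promoter window of 2500 bases (3.58%, p = 0.178), without replicate 1 (3.71%, p = 0.871) or without replicate 2 (3.93%, p = 0.0792). The replicated list, made by an overlap rule, put introns at 43.8%, above its random share (two-sided permutation p = 0.0396).

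Genes for the products of the gastric epithelium had accessible promoters more often than other genes with promoters of like CpG content. Of 23 genes in this list, 12 (52.2%) had a region at the promoter against 21.4% expected. The highest signal values were at Gkn1, a gastrokine of surface mucous cells, with 10.3 (chromosome 6, 87350814 to 87351384), at Cldn18, a tight junction protein with a stomach isoform, with 10.3 (chromosome 9, 99716873 to 99717641), and at Anxa10, an annexin, with 9.72. Atp4a, a subunit of the proton pump of parietal cells, and Aqp5, a water channel, were among the members with no region at the promoter. The two-sided exact test within CpG deciles gave p = 0.000162, or 0.000554 after Benjamini-Hochberg adjustment over 24 lists. The call rests on the CpG deciles, since 12.9 genes would be expected without them (Fisher's exact test, adjusted p = 0.870), and it was lost in replicate 2 alone (8 genes, adjusted p = 0.0989) and in the 15824 regions of highest signal (4 genes, adjusted p = 0.581).

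Transcription factors of the gastric epithelium had a region at 17 of 21 promoters against 13.8 expected, a difference that did not pass the exact test (adjusted p = 0.116). The highest signal values were at Esrrg, an orphan nuclear receptor, with 12.8 (chromosome 1, 187997599 to 187998333), at Klf5, a Krüppel-like factor of epithelia, with 12.8 (chromosome 14, 99298236 to 99299484), and at Sox21, an HMG box factor, with 11.5. Foxq1 and Hnf1b were among the members with no region at the promoter. Replicate 1 alone gave 17 genes against 12.8 expected (exact test, adjusted p = 0.0455), without the CpG deciles the adjusted p was 0.0394, and the replicated list gave 20 of 21 against 16.3 (exact test, adjusted p = 0.0393). All 16 housekeeping genes had an accessible promoter, led by Pgk1 (15.1), Psmb2 (14.5) and Rplp0 (13.9), against 13.7 expected (exact test, adjusted p = 0.225, or 0.0011 without the CpG deciles).

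Regulators of the gastric mesenchyme had accessible promoters less often than their CpG content would give. Of 18 such transcription factors, 7 had a region against 15.3 expected (exact p = 1.7e-06, adjusted 8.18e-06). Gli3, a mediator of Hedgehog signalling, had the highest signal of the list, 8.92, followed by Nr2f2, a nuclear receptor of mesenchyme and veins, with 7.79, and Six2, a homeobox gene of the pyloric region, with 6.94. Barx1, a homeobox gene of the stomach mesenchyme, and Foxf2, a forkhead gene of the gut mesenchyme, had no region at the promoter in the main catalogue. The replicates differed here, with 3 accessible promoters in replicate 1 and 10 in replicate 2, both below expectation (exact test, adjusted p = 1.26e-08 and 0.00561), and Barx1 was listed in replicate 2 with a signal of 6.53. The shortfall ended in the less strict replicated list, with 16 of 18 genes accessible against 17.1 expected (exact test, adjusted p = 0.387), and without the CpG deciles, with 10.1 expected (adjusted p = 0.190).

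Smooth muscle genes had a region at 11 of 18 promoters against 9.67 expected (exact test, adjusted p = 0.601). Sorbs1, an adaptor of cell adhesion, had a signal of 16.2 (chromosome 19, 40513018 to 40514129), Tpm1, a tropomyosin, 8.95 and Synm, an intermediate filament protein, 8.89. Acta2 and Cnn1, which encode smooth muscle actin and calponin, had no region at the promoter in the main catalogue, but were listed in replicate 2 with signals of 9.13 and 4.73. Replicate 2 had 16 accessible promoters of this list against 9.40 expected (exact test, adjusted p = 0.000343), and replicate 1 had 7 against 8.77 (adjusted p = 0.458). The optimal and the replicated list gave 15 and 18 genes (exact test, adjusted p = 0.0141 and 0.00113). Of 5 genes of interstitial cells of Cajal, the pacemaker cells of the gut, Etv1 (13.9) and Kit (5.63) had an accessible promoter while Ano1 and Gpr20 did not (2 against 2.95 expected, exact test, adjusted p = 0.576).

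Neural, vascular and endocrine genes were accessible less often than expected. Enteric neurons and glia had 4 of 19 promoters against 12.6 expected (exact p = 1.36e-06, adjusted 8.15e-06), and these included Ret, the receptor of GDNF (7.61), Elavl4, an RNA-binding protein of neurons (6.27), and Uchl1, a neuronal deubiquitinase (5.91), but neither Ascl1 nor Chat. The endothelial list had 4 of 15 against 8.25 expected (exact p = 0.00906, adjusted 0.0198), with Erg (6.70), Prox1 (4.59) and Kdr (3.59) accessible and Cdh5 and Emcn not. In replicate 1 and replicate 2 alone the endothelial list had 2 and 1 accessible promoters and the enteric list 2 in each, all below expectation. Neither Elavl4 nor Kdr had a region at the promoter in a replicate's own thresholded list. Gastric endocrine genes had 4 of 16 against 8.91 expected (exact p = 0.00312, adjusted 0.00937), with Chgb, a granin of secretory granules, at 12.5, Isl1 at 12.01 and Arx at 5.99, while Chga and Gast, which encodes gastrin, had no region. The list of Hedgehog, Wnt, BMP and FGF signalling had 11 of 20 against 16.0 expected (exact p = 0.00437, adjusted 0.0117), led by Axin2 (10.9), Fgfr2 (10.7) and Smo (8.54), with Bmp4 and Fgf10 among those without a region. In the replicated list none of these 4 shortfalls passed the test, with 14, 12, 9 and 20 genes accessible against 14.9, 10.5, 11.2 and 18.3 expected. By the exact test the signalling list also missed the threshold in each replicate alone (adjusted p = 0.0746 and 0.0618), in the optimal list (0.0693), without the CpG deciles (11.2 expected) and with a promoter window of 2500 bases (0.0998), and the endothelial list missed it with that window (0.0622).

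Hox genes were the lists with the largest shortfall of accessible promoters in percentage points of a list's genes. Of 15 genes of paralogs 1 to 5, Hoxa1 (signal 7.12; chromosome 6, 52158034 to 52159448) and Hoxa5 (6.93) were accessible, against 11.1 expected (exact p = 1.14e-07, adjusted 1.36e-06), while Hoxa2 and Hoxa3 were among those that were not. Of 8 genes of paralogs 6 to 8, among them Hoxa6 and Hoxa7, 0 were accessible against 6.09 expected (exact p = 1.09e-06, adjusted 8.15e-06). Of 16 genes of paralogs 9 to 13, Hoxb9 (3.59) alone was accessible against 13.5 expected (exact p = 2.89e-13, adjusted 6.94e-12), and Hoxa10 and Hoxa11 were among the rest. Neither replicate's own thresholded list had a region at the Hoxb9 promoter. Replicate 2 had 8 accessible promoters of paralogs 1 to 5 (exact test, adjusted p = 0.171) where replicate 1 had 1 (adjusted p = 7.92e-07). In the replicated list paralogs 1 to 5 reached 13 of 15, whereas paralogs 6 to 8 (3 of 8, exact test, adjusted p = 0.000802) and 9 to 13 (9 of 16, adjusted p = 1.61e-05) stayed below expectation. The exact test treats the genes of a Hox cluster as independent, although neighbours may share their accessibility, so these p-values are likely too small.

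Lists of other organs mostly lay below or near expectation, with single members at high signal. A region in the window of a gene may lie at the start of a neighbour, so such a signal is not shown to belong to the named gene. Forebrain neuron genes had 3 of 13 promoters against 9.53 expected (exact p = 1.82e-05, adjusted 7.29e-05), with Satb1 (8.03), Lhx2 (6.28) and Camk2a (5.10) accessible and Dlx2 and Emx1 not. Germ cell genes had 2 of 12 against 5.77 (exact p = 0.00736, adjusted 0.0177), namely Dazl, an RNA-binding protein of germ cells (14.0), and Stra8 (4.93), but not Acrv1 or Ddx4, and in replicate 1 alone the adjusted p was 0.0532, in the 15824 regions of highest signal 0.0546 and with a promoter window of 2500 bases 0.0622. Lens and photoreceptor genes, Crx and Cryaa among them, had 0 of 12 against 3.46 (exact p = 0.0129, adjusted 0.0257), with an adjusted p by the exact test of 0.0588 in replicate 1, 0.0523 in replicate 2 and 0.196 in the 15824 regions of highest signal. For forebrain neurons the replicated list ended the call (9 genes, exact test, adjusted p = 0.30).

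The remaining 8 lists did not pass the test, with adjusted p from 0.116 to 0.699. Forestomach squamous epithelium had 4 of 19 accessible promoters against 5.96 expected, with Perp, a desmosomal protein, at 11.6, Itgb4 at 6.28 and Sfn at 5.47, and Bnc1 and Col17a1 without. The pancreas list had 4 of 14 against 5.46, and its strongest members were the transcription factor genes Mafa (14.0), Nkx6-1 (11.1) and Pdx1 (9.38), while the digestive enzyme genes Amy2a5 and Cel had none. The intestinal list had 4 of 17 against 5.16, with Muc2 at 10.2, Isx at 8.28 and Satb2 at 4.61, and Alpi and Apoa4 without; in the replicated list it had 12 against 6.82 expected (exact test, adjusted p = 0.00328), and in replicate 2 alone 2 against 4.94 (adjusted p = 0.0408, below expectation). Skeletal muscle had 2 of 14 against 4.83, Actn3 (14.7) and Mylpf (11.7), but not Acta1 or Ckm. Lung epithelium had 2 of 10 against 3.30, Abca3 (10.0) and Foxj1 (6.50), but not Lamp3 or Napsa. Leukocytes had 2 of 14 against 3.35, Ikzf1 (4.84) and Cd68 (2.92, in neither replicate's own thresholded list), but not Adgre1 or Cd19. Erythroid cells had 3 of 11 against 3.79, Klf1 (8.61), Ank1 (4.42) and Epor (3.75), but not Alas2 or Gata1. Hepatocytes had 1 of 14 against 1.91, Ttr (6.62), a carrier of thyroid hormone, while Ahsg and Alb had none. Without the CpG deciles the forestomach, leukocyte, skeletal muscle, hepatocyte, intestinal and lung lists passed Fisher's exact test as below expectation (adjusted p from 0.0011 to 0.0394), and the erythroid list did with a promoter window of 500 bases (1 gene, adjusted p = 0.0472).

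**Figure D1:**
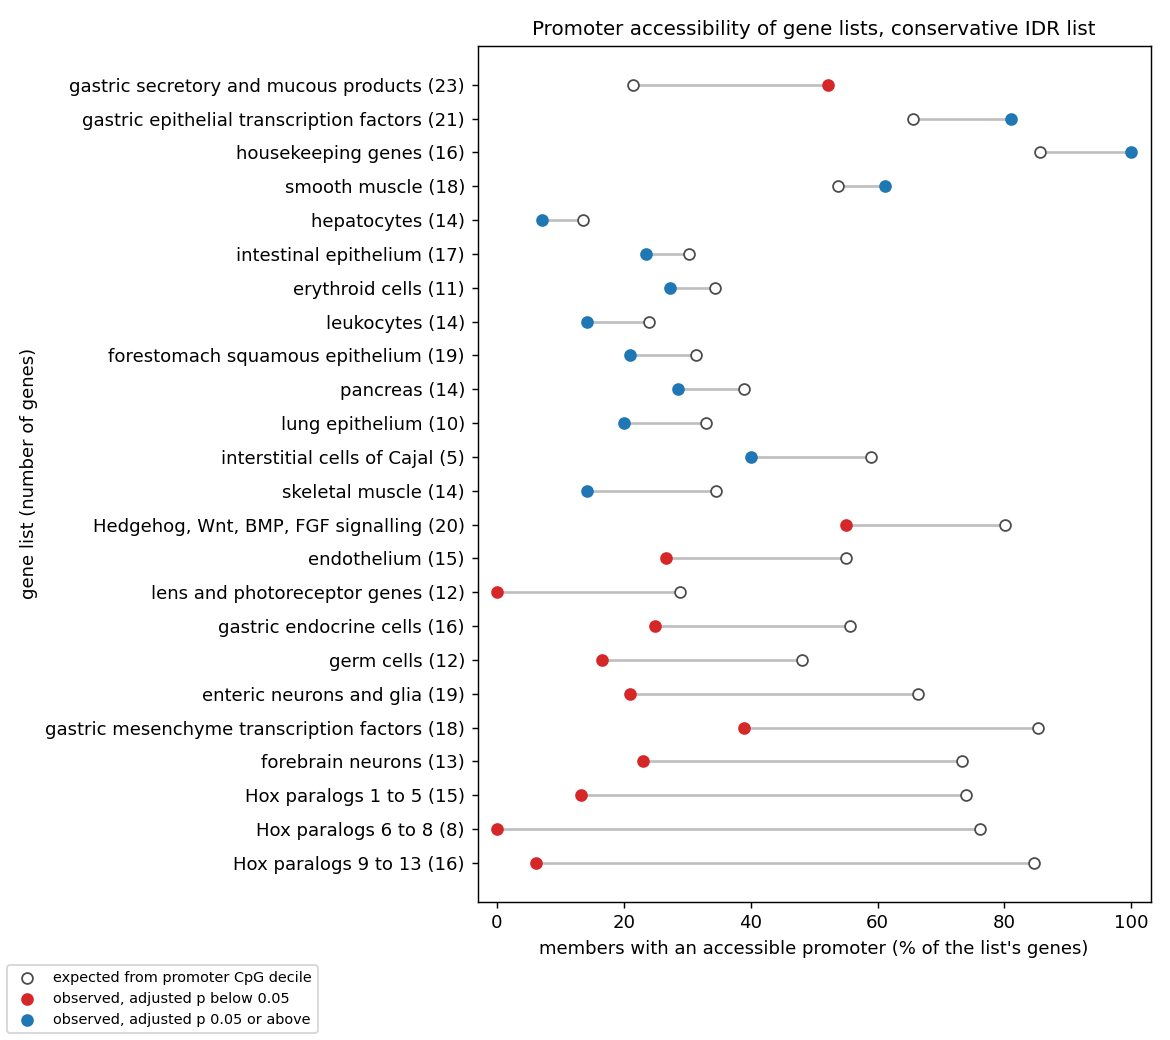
Share of the genes of each list with an accessible promoter, in percent of the list's genes, in the main catalogue; open circles are the shares expected from the CpG deciles and filled circles the observed ones, red where the adjusted p is below 0.05. Gastric secretory and mucous products (52.2% against 21.4%) passed the exact test above expectation and 11 lists, with the Hox lists at the bottom, passed it below, while gastric epithelial transcription factors, housekeeping genes and smooth muscle lie above expectation and the remaining lists below it without passing.

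Distal regions, those over 1000 bases from any annotated start of a protein-coding gene, were gathered around the transcription factors of the gastric epithelium. These 21 genes had a mean of 4.00 distal regions within 50000 bases (SD 2.83 over genes) against 1.26 for random lists matched on local gene density, and 20 of the 21 had at least 1. Foxq1, a forkhead gene without a region at its promoter, had 9, and Elf3, an ETS factor of epithelia chosen after its value was seen, had 11. The list of Hedgehog, Wnt, BMP and FGF signalling had a mean of 2.75 (SD 3.13) against 1.15, with 11 distal regions at Id1, a target of BMP signalling, and 9 at Hes1, a target of Notch signalling, both also chosen after their values were seen. The two-sided permutation test gave p = 2e-05 for the first list, the smallest that 100000 random lists can give, and 0.00086 for the second, or 0.00048 and 0.0103 after adjustment over 24 lists. In the permutation test the signalling list was no longer past the threshold in replicate 1 alone (adjusted p = 0.0608), without matching on gene density (0.0722) or in the 15824 regions of highest signal (0.491). The list also holds Notch1 and Hes1, members of the Notch pathway, and without these 2 genes the mean was 2.33 against 1.14 (permutation test, adjusted p = 0.104), while without Id1 and Hes1 it was 1.94 against 1.14 (adjusted p = 0.321), both alternatives chosen after the data were seen. The call for this list thus rests on a few genes.

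The other 22 lists did not pass this permutation test. Gastric secretory and mucous products had a mean of 2.70 distal regions against 1.53 (permutation test, adjusted p = 0.0771) and forestomach squamous epithelium 2.68 against 1.54 (adjusted p = 0.104). Secretory products passed the permutation test in replicate 1 alone (adjusted p = 0.0142), in the optimal list (0.0405), in the replicated list (0.0193) and with a window of 100000 bases (0.0258), and forestomach epithelium with that window (0.0280). Smooth muscle, with a mean of 2.50 against 1.49 (permutation test, adjusted p = 0.209), passed in replicate 2 alone (adjusted p = 0.0190) and in the replicated list (0.00144). Hox paralogs 9 to 13 had a mean of 0.0625 in replicate 1 alone, but neighbouring Hox genes share distal regions, so no call is read from this test for the Hox lists. Neighbouring genes in the secretory and forestomach lists can share distal regions too. The random lists do not match this, so the p-values of these lists may be too small. The 5 genes of interstitial cells of Cajal had a mean of 2.80 against 1.02 in the permutation test (adjusted p = 0.256). Housekeeping genes (2.38), endothelium (2.13), lung epithelium (2.10), lens and photoreceptor genes (2.00), intestinal epithelium (1.94), erythroid cells (1.73), pancreas (1.71), germ cells (1.58), mesenchyme transcription factors (1.33) and forebrain neurons (1.31) also had means above those of their random lists. Hox paralogs 6 to 8 (1.75), Hox paralogs 1 to 5 (1.60), leukocytes (1.36), skeletal muscle (1.21), Hox paralogs 9 to 13 (1.19), hepatocytes (1.14), endocrine cells (1.06) and enteric neurons and glia (0.737) had means below those of their random lists.

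Among all 21827 protein-coding genes, those with the most distal regions were Sgms1 with 15, a sphingomyelin synthase, and Tcf7l2 with 14, a transcription factor of Wnt signalling. Mecom, a zinc finger transcription factor, Plekha6, Lad1, an anchoring filament protein of epithelia, and Vamp2, a vesicle membrane protein, had 13 each. Lmo7, Krt78, Krt8, a keratin of simple epithelia, and Dgat2, an enzyme of triglyceride synthesis, had 12 each. Random genes of the same local gene density had a mean between 1.11 (Tcf7l2) and 1.957 (Vamp2). They were not matched on the number or spread of starts, so a long gene with several starts had more sequence searched. Krt78 and Krt8 lie close together on the same chromosome and can share distal regions. The mean of all protein-coding genes was 1.49.

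**Figure D2:**
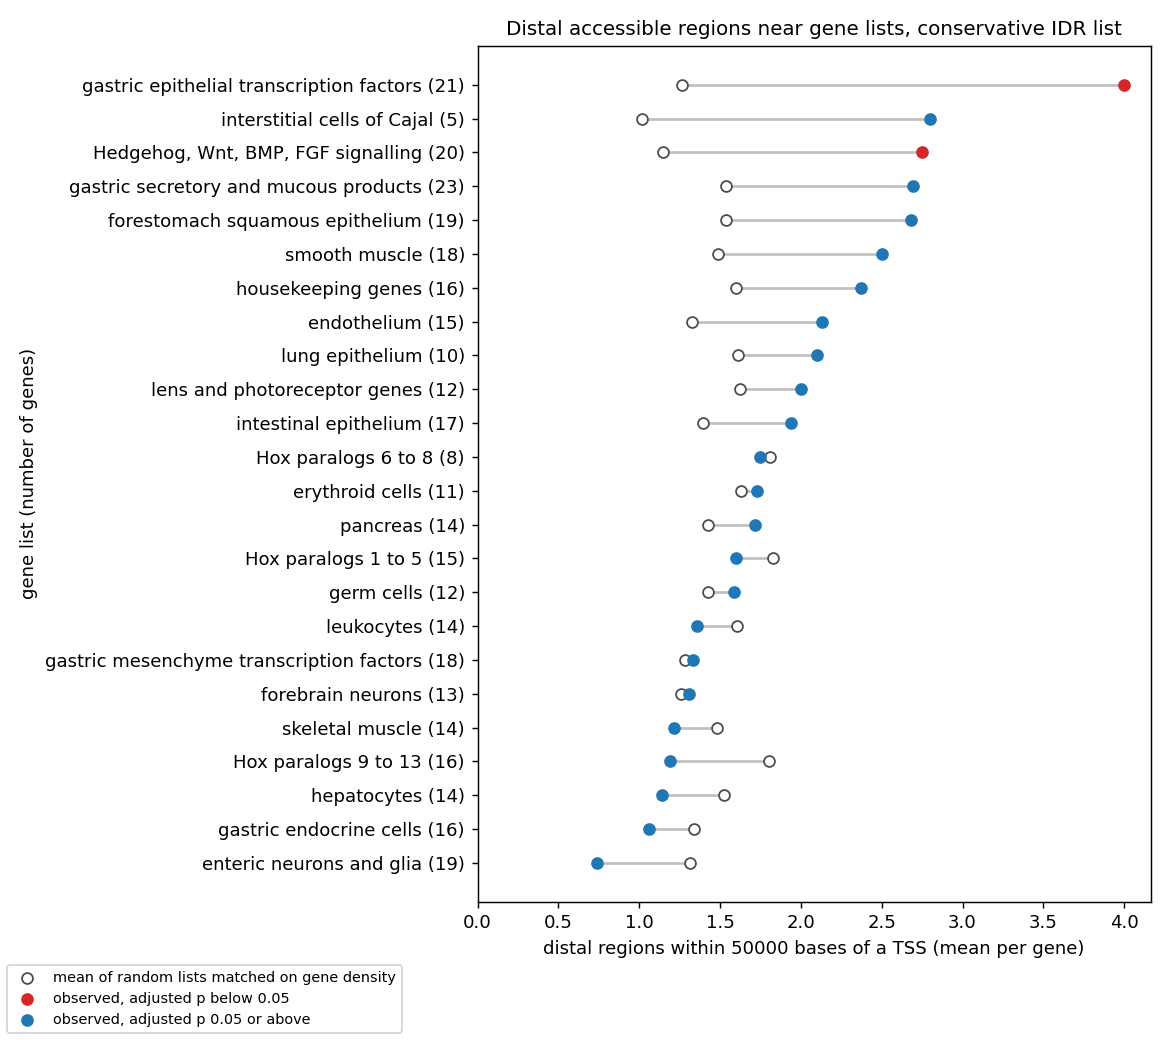
Mean number of distal regions within 50000 bases of a start per gene, for each list, in the main catalogue; open circles are the means of random lists matched on gene density and filled circles the observed means, red where the adjusted p is below 0.05. Gastric epithelial transcription factors reach 4.00 against 1.26.

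The sites of CTCF, an architectural factor, and of HNF4, AP-1, ETS and KLF proteins were concentrated at the summits of distal regions. The CTCF consensus was in 628 of 19767 summit windows (3.18%) and in 24 windows 1000 bases away, a ratio of 26.2 (95% interval 17.4 to 41.2). HNF4, a nuclear receptor of endoderm, had a ratio of 10.9 (6.97 to 18.0), AP-1, a dimer of FOS and JUN proteins, 9.20 (8.22 to 10.3; 15.7% of summit windows), and KLF and SP factors 8.68 (7.35 to 10.3). The full site of NFI had a ratio of 14.0 on 14 and 1 windows (2.13 to 592), and the ETS consensus 12.5 on 25 and 2 windows (3.12 to 109). The shorter consensus of ERG, also an ETS factor and named after its value was seen, had a ratio of 1.17 (1.13 to 1.22). FOXA and GATA sites, named after their values were seen, had ratios of 2.89 (2.51 to 3.34) and 2.04 (1.76 to 2.37). The FOXA consensus is also that of FOXF, so its ratio cannot be credited to endoderm rather than mesenchyme factors. The lowest ratios past the threshold were those of PHOX2, a homeobox factor of autonomic neurons (0.111 on 1 and 9 windows, 0.00253 to 0.802), GLI, the factor of Hedgehog signalling (0.353, 0.114 to 0.938), and the CDX and posterior HOX consensus (0.397, 0.359 to 0.439).

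By the two-sided exact McNemar test, 23 of 30 consensus sequences passed the threshold in distal regions, with FOXA and FOXF counted separately. The adjusted p was 7.88e-154 for CTCF, 8.55e-45 for HNF4, 8.57e-246 for KLF and SP, 0.00146 for NFI, 9.97e-06 for ETS, 0.0307 for PHOX2, 0.0459 for GLI and 2.92e-85 for CDX and posterior HOX, and that of AP-1 was too small for double precision. Summit windows held 54.1% G and C against 46.3% in the flanks. Against 20 permuted consensus sequences of the same bases, the 6 high ratios and those of FOXA and GATA lay above the whole range, whereas PHOX2, GLI and CDX lay inside it. By the exact test the GLI call also ended without replicate 1 (ratio 1.67, adjusted p = 0.342) and without replicate 2 (0.556, adjusted p = 0.509), and the NFI and PHOX2 calls ended without replicate 1 (adjusted p = 0.0781 for each).

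At promoters the sites of NRF1, ETS, KLF and SP factors and NFY, factors of broadly used promoters, were the most concentrated. NRF1 was in 92 of 11881 summit windows and 0 flank windows, at least 30.7-fold higher against a floor of 3 windows, with an exact 95% lower limit of 24.4 for the ratio itself. ETS had a ratio of 29.0 (13.1 to 80.1) on 174 and 6 windows. The shorter consensus of ERG, also an ETS factor and named after its value was seen, went the other way with 0.767 (0.723 to 0.813). KLF and SP had a ratio of 21.7 (17.9 to 26.6, 19.6% of summit windows) and NFY 8.41 (7.20 to 9.87, 12.7%). CTCF had 7.44 (3.70 to 17.0) and RFX 6.50 on 13 and 2 windows (1.47 to 59.3). The lowest ratios past the threshold were those of CDX and posterior HOX (0.187, 0.155 to 0.224), NKX2 and NKX3 (0.222, 0.168 to 0.289) and TCF and LEF (0.296, 0.180 to 0.472). By the exact McNemar test 17 of 30 passed, with adjusted p of 2.02e-27 for NRF1, 4.40e-43 for ETS, 3.04e-273 for NFY, 1.44e-11 for CTCF, 0.0138 for RFX, 7.86e-104 for CDX, 1.79e-37 for NKX and 5.67e-08 for TCF and LEF, and a value too small for double precision for KLF and SP; the RFX call ended in the regions of highest signal (adjusted p = 0.0586). Promoter summits held 66.5% G and C against 47.1% in the flanks, and the ratios of KLF and SP, CTCF, CDX, NKX and TCF lay inside the range of their permuted sequences.

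**Figure D3:**
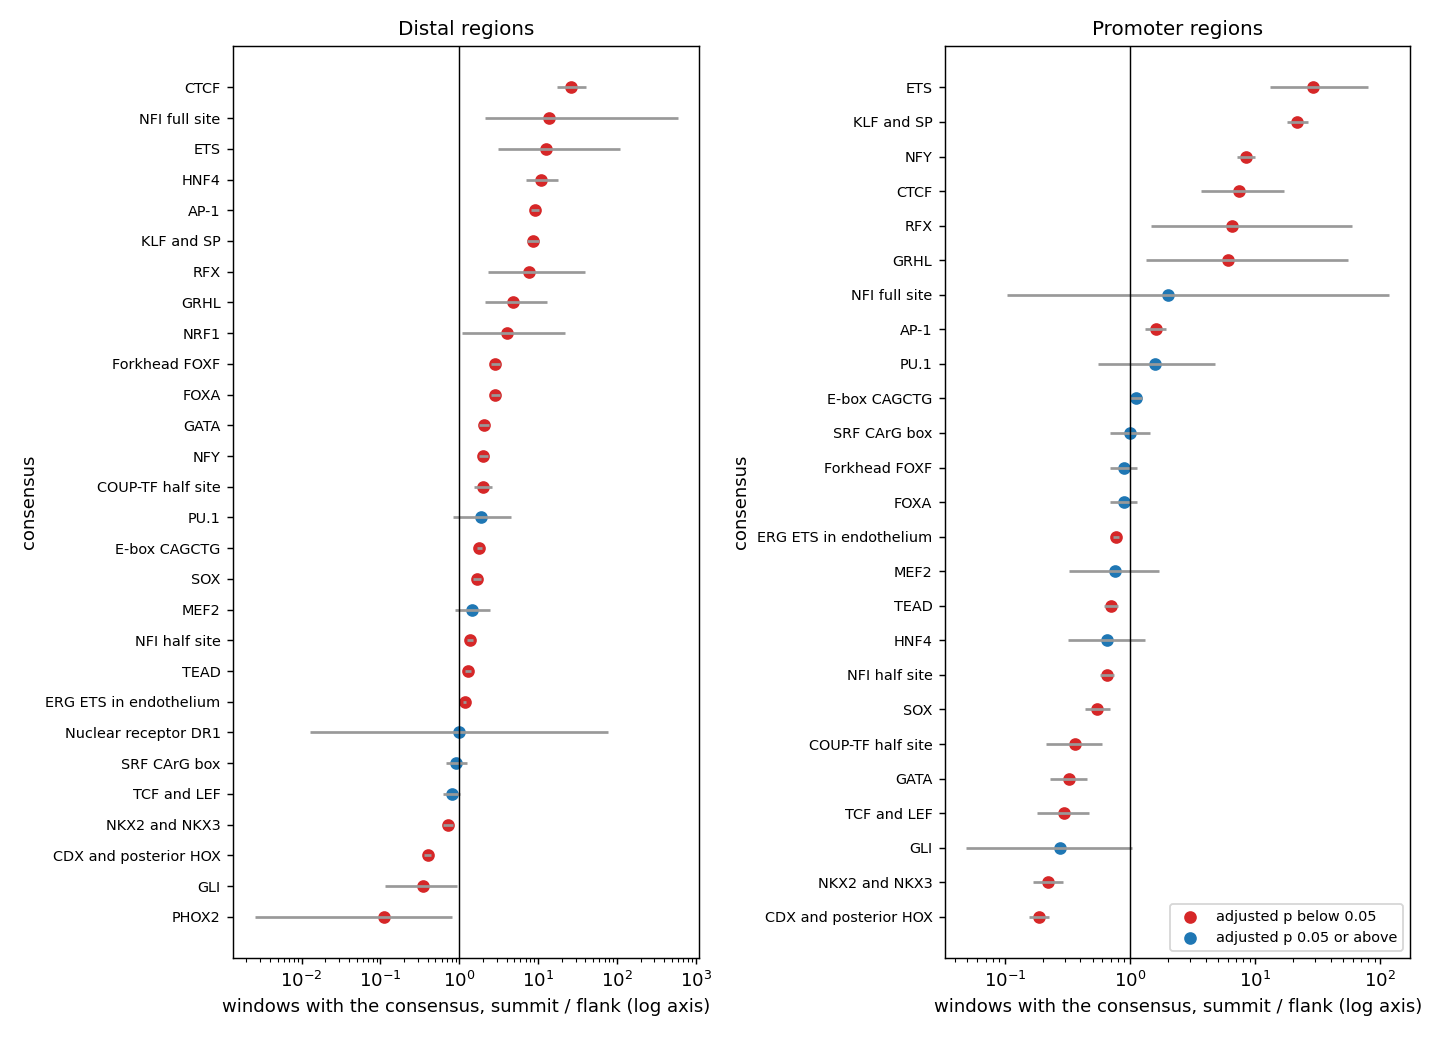
Ratio of windows with each consensus at the summit to those in the flank, on a log axis, for distal (left) and promoter regions (right); bars are 95% intervals, and consensus sequences without a flank window, NRF1 at promoters among them, are not drawn. CTCF leads in distal regions with 26.2 and ETS among the drawn ones at promoters with 29.0.

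The X chromosome held few accessible regions for its length. It had 3.48 regions per Mb against 12.2 on the median autosome, a ratio of 0.286. The autosomes ran from 8.91 on chromosome 14 to 19.4 on chromosome 11. Starts of protein-coding genes on the X chromosome had a density of 0.711 of the median autosome. The Y chromosome held 3 regions.

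The regions listed in 1 replicate alone included a few near genes of smooth muscle, mesenchyme, signalling and Hox lists in replicate 2, and a few near genes for gastric products in replicate 1. Of the regions with the highest signal that overlap nothing in the other replicate's less strict list, those of replicate 2 were nearest to Uty (signal 12.1, at the promoter), Slc1a6 (12.01), Gucy1b1 (11.9), Ddx3y (11.9, at the promoter) and Hspa12b (11.7). Uty and Ddx3y lie on the Y chromosome, and Gucy1b1 encodes a subunit of soluble guanylate cyclase, the nitric oxide receptor of smooth muscle. Those of replicate 1 were nearest to Lpin1 (11.1), Csnk1g3 (9.81), Ccdc121 (9.79), Pag1 (9.76) and Rnf125 (9.56), at 10437 to 367359 bases from the start. Smooth muscle genes had 12 such regions within 50000 bases in replicate 2 and 3 in replicate 1, mesenchyme transcription factors 7 and 1, the Hedgehog, Wnt, BMP and FGF list 6 and 0, Hox paralogs 1 to 5 had 9 and 0, and gastric secretory products 0 and 6, out of 1400 and 1013 regions. Lists of other organs also differed, with 4 and 0 for lens and photoreceptor genes and 0 and 2 for both germ cells and hepatocytes. These counts were made after the data were examined. For a comparison with random lists matched on gene density, a region was counted once for each listed gene in reach, unlike in the counts above. So counted, 99.7% of random lists lay below the mesenchyme list and 99.4% below the signalling list in replicate 2. In replicate 1, 99.2% lay below the secretory list, and no share was adjusted over the 24 lists. Close members of these lists can share regions, so the shares may be too high. Neighbouring Hox genes share regions, so no such value is given for them.

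In all, 27296 regions of replicate 1 and 25178 of replicate 2 passed the threshold within each replicate. Of these, 72.6% and 78.8% overlapped a region of the other replicate by at least 1 base, and 58.4% of the covered bases were shared. Most of the rest were in the other replicate's less strict list, which held 96.3% of the regions of replicate 1 and 94.4% of those of replicate 2 and left 1013 and 1400. Across the 19817 regions of replicate 1 shared with replicate 2, the signal values had a Spearman rho of 0.782, with 0.858 for 10300 regions at promoters and 0.709 for 9517 elsewhere. Regions are not independent replicates, so no p is given.

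**Figure D4:**
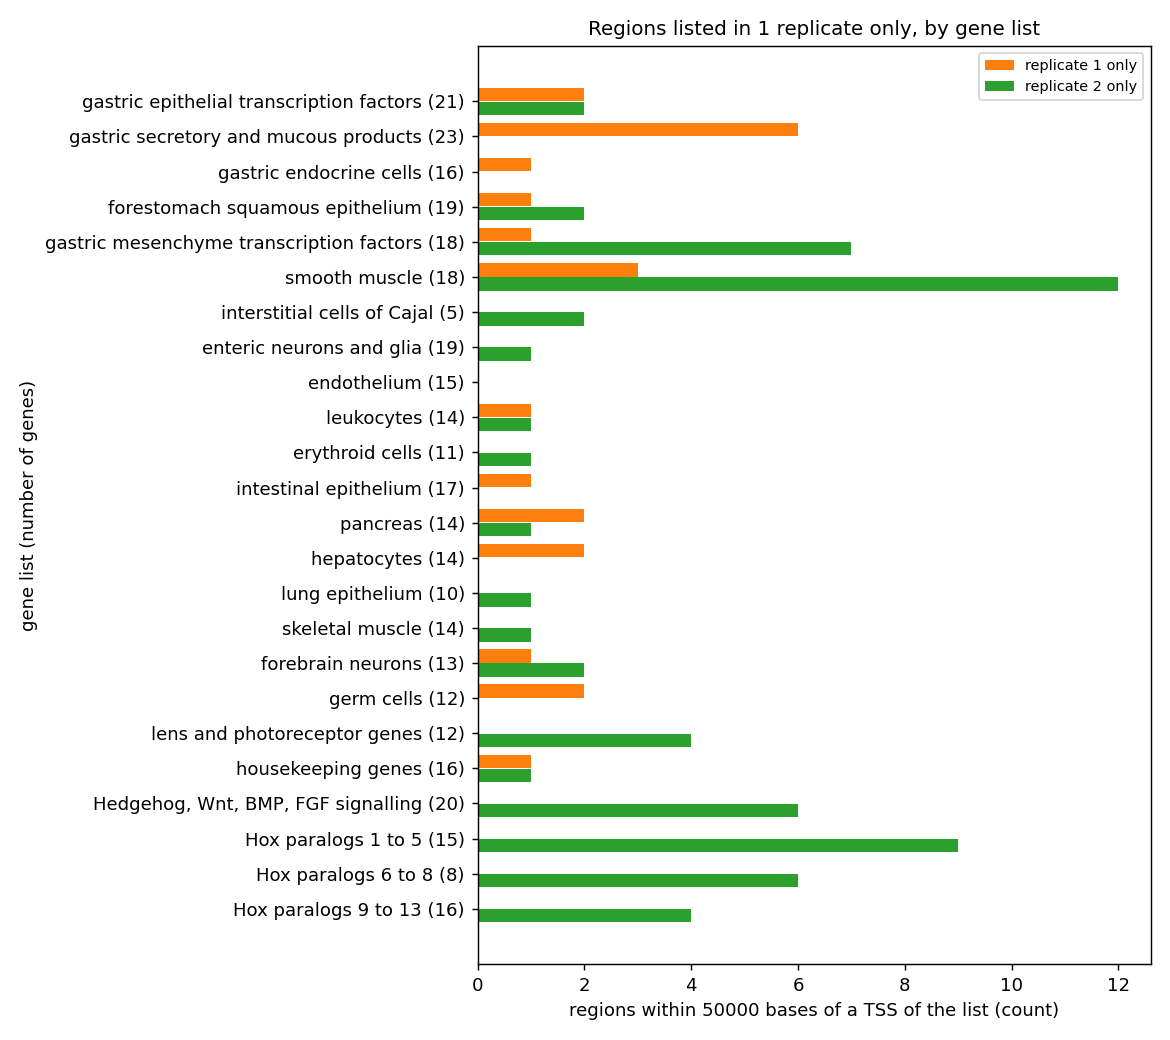
Number of regions within 50000 bases of a start of each gene list that were listed in replicate 1 only (orange) or replicate 2 only (green). Smooth muscle reaches 12 in replicate 2 and 3 in replicate 1, and gastric secretory products 0 and 6.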

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

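Chosen only after the result was seen were the tests of a lower share of epithelium alone, of the shares of male and female pups, of mitochondrial copies, and those that count forestomach genes as epithelial; no biological explanation set by the design was tested, since there is 1 group.

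Some peaks with scores as high as those in the thresholded lists are missing from them, a signal in data that the comparisons do not use. The ranked lists hold 257 such peaks in replicate 1 and 206 in replicate 2 with a score of at least 540, and 302 for the conservative and 315 for the optimal combined list. Of the 302 peaks, 120 lie on sequences outside the chromosomes, and the rest form 86 regions; the highest signal among the 302 was 50.3.

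Of 1013 regions listed in replicate 1 only, 8 lay near genes of the epithelial lists (gastric epithelial transcription factors and secretory products) and 4 near mesenchymal or smooth muscle genes, against 2 and 19 of 1400 in replicate 2 only (odds ratio 19.0, 95% interval 2.27 to 221, or 10.7, 1.74 to 71.4, with the forestomach list counted as epithelial, which had 1 and 2), and the epithelial difference came from secretory products (6 and 0), not from transcription factors (2 and 2). The intervals of these odds ratios treat regions as independent, although several can lie near 1 gene. The 3 smooth muscle regions of replicate 1 only lay near 1 gene, and the 12 of replicate 2 only near 9 genes. These intervals are therefore likely too narrow, and the contrast uses list counts made after the data were examined. A difference in list length and threshold stays open. With the 20000 regions of highest signal in each replicate the odds ratio was at least 9 against a floor of 3. Its interval ran from 1.34, on 3 and 0 regions against 1 and 9. This argued against the length of the thresholded lists, for the gastric lists alone and on few regions. With the forestomach list the interval began at 0.953 (3 and 0 regions against 2 and 9) and so held 1. The less strict lists, which decide what is found in 1 replicate only, were not equalised (63338 regions in replicate 1 and 67564 in replicate 2). Different shares of epithelial and mesenchymal cells in the pools are a candidate explanation. As predicted in advance for it, HNF4 or GRHL sites were 2.54 times as frequent in replicate 1 only (1.03 to 6.27). This came through HNF4 (13 and 5 windows) and not GRHL (1 and 2). Sites outside that prediction differed too, with ratios of 0.0953 for CArG or MEF2 (0.0296 to 0.307) and 0.387 for CTCF (0.214 to 0.699). The ratios were 6.07 for GATA and 2.01 for FOXA, against 1.01 for AP-1. The shares of windows with a site were not matched on GC content. GC content (medians 47.7% and 50.8%) stays open: after matching the odds ratio was 10.5 (0.708 to 550), an interval that holds 1, as was set in advance for that cause, but also the unmatched 19.0, so it was read as undecided after the result was seen, the regions being too few. A lower share of epithelium alone cannot be told apart from more mesenchyme either, with an odds ratio of 2.38 (0.0323 to 55.1) of mesenchyme and smooth muscle against endothelium, neurons and leukocytes, replicate 2 only over replicate 1 only, on few regions.

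Promoters of the Y-linked genes Eif2s3y, Uty and Ddx3y were listed in replicate 2 with signal values from 11.4 to 12.1, and in neither list of replicate 1. Replicate 1 did list other regions of the Y chromosome. The highest, nearest to Gm21860, had a signal of 15.7 in either replicate. The region at 259079 to 259394 had 4.79 in the less strict list of replicate 1, against 13.8 for the overlapping thresholded region of replicate 2. The threshold of the less strict list of replicate 1 was argued against. All 631 autosomal promoter regions of replicate 2 with signal values from 11.4 to 12.1 (100%) were in that list. Their presence in the thresholded list of replicate 1 was not counted. Different shares of male and female pups may account for the Y-linked difference, but the test of this cannot decide. X-linked regions were 2.69 times as frequent among those of replicate 1 only (1.53 to 4.72). Over all regions listed the ratio was 1.05 (0.928 to 1.18), with 554 of 27296 and 488 of 25178, an interval that holds 1. The share of listed regions that are X-linked does not measure the share of female pups. The labels give pools of male and female pups for both replicates, without the number of each.

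The highest signal values of the catalogue lay outside promoters, up to 59.4 against 27.1. Reads of mitochondrial DNA placed at nuclear copies of it may account for part of them, since 4 of the 10 regions of highest signal outside promoters (40%) match the mitochondrial genome, against 13 of 19767 (0.0658%). The other 6 of these regions, that nearest to Pak3 included, have no such match and stay unexplained.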

How the results depend on the processing

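The 2 alternatives that leave genes out of the distal signalling list were chosen after the results were seen, and both lost the call (adjusted p by permutation 0.104 and 0.321). Of 192 values over 24 promoter lists and their alternatives, 142 kept direction and side of the threshold, 21 lost the call, 15 gained it and 14 turned; of 194 for distal regions these were 148, 5, 10 and 31, of 180 for distal motifs 149, 15, 10 and 6, and of 150 for promoter motifs 111, 12, 16 and 11. The high share at promoters and the low density on the X chromosome kept direction under each alternative run, and so did distal regions at gastric epithelial transcription factors, with an adjusted p of 0.00048 or lower. Read depth is unknown, so what depth limits could not be assessed; unless stated, the cause of a change was not tested.

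With other lists the catalogue held 79857 (replicated) or 89229 (pseudoreplicated) regions, by construction 15824 for those of highest signal and 64590 for peaks as listed. A reciprocal overlap of 50% gave shared regions of 68.9% (replicate 1) and 74.7% (replicate 2), the 20000 of highest signal 76.3% for either, and pseudoreplicated lists 67.7% for replicate 2 and a rho of 0.753; rho was 0.858 at promoters and 0.709 elsewhere. Passing distal lists numbered 4 with a window of 100000 bases, 4 with the replicated list and 1 without gene density strata; promoter motifs numbered 11 against permuted sequences.

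Promoter lists turned, without passing unless stated. With the replicated list the counts were 9 for forestomach, 4 for interstitial cells of Cajal, 12 for endothelium, 6 for leukocytes, 7 for erythroid cells, 12 for intestine (passing), 4 for hepatocytes, 5 for lung and 20 for signalling genes. With the regions of highest signal 10 epithelial transcription factors and 6 smooth muscle genes lay below expectation, with a promoter window of 2500 bases 3 hepatocyte genes above it, and without CpG strata 12 secretory genes below it, the expected count alone having changed. The exon share fell to 2.65% for the regions of highest signal and the intron share was 43.8% in the replicated list. Both turned and passed the two-sided permutation test (p = 0.0198 and 0.0396).

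Distal means turned across expectation without passing. With a window of 100000 bases they were 2.94 (endocrine), 2.06 (mesenchyme), 3.36 (leukocytes), 2.93 (skeletal muscle) and 2.08 (forebrain). With 25000 they were 0.611 (mesenchyme), 0.545 (erythroid), 0.571 (pancreas), 0.80 (lung), 0.667 (germ cells) and 1.12 (Hox 6 to 8). For the regions of highest signal they were 0.333 (mesenchyme, lens), 0.643 (skeletal muscle) and 0.417 (germ cells). Without density strata they were 1.33 (mesenchyme), 1.31 (forebrain), 1.60 (Hox 1 to 5) and 1.75 (Hox 6 to 8). The optimal list gave 1.82 (erythroid) and 1.5 (germ cells), and the replicated list 4.57 (skeletal muscle), 3.85 (forebrain), 7.27 (Hox 1 to 5) and 7.12 (Hox 6 to 8).

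Against permuted sequences these ratios turned: in distal regions CArG 1.02, NRF1 0.943 and CDX 1.23; at promoters FOXA 3.32, GATA 1.25, HNF4 1.22, NFI 0.988, CDX 1.72, FOXF 3.02, the E-box 0.371, ERG 1.29 and MEF2 5.04. TCF in distal regions of highest signal was 1.05.

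With either replicate left out, values that turned in at least 1 case ranged from 3.71 to 3.93% for exons, 7 to 16 for smooth muscle promoters, and in distal means from 0.889 to 1.39 for mesenchyme, 1.27 to 1.27 for erythroid cells, 1.00 to 1.36 for skeletal muscle, 0.923 to 1.15 for forebrain, 1.25 to 1.33 for lens and 0.467 to 1.73 for Hox 1 to 5. Distal ratios ranged from 0.785 to 1.90 for CArG (passing the exact test without replicate 1, adjusted p = 9.68e-05) and 0.556 to 1.67 for GLI, and promoter ratios from 0 to 2 for NFI and 0.875 to 1.80 for GRHL.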

Other observations

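The gene families here, and the other values in this part, were all chosen after the strongest regions and the Hox lists had been seen. Zinc finger genes named Zfp had an accessible promoter in 326 of 394 cases against 252.1 expected from CpG content (exact test, adjusted p = 6.3e-23 over 7 families). Proteasome genes (47 of 50 against 39.6, adjusted p = 0.00519), genes of respiratory complex I (31 of 32 against 25.3, adjusted p = 0.00519) and ribosomal protein genes (87 of 98 against 79.6, adjusted p = 0.0293) were also above expectation by the exact test. Olfactory receptor genes had 3 of 1133 against 89.95 (exact test, adjusted p = 1.02e-40) and vomeronasal receptor genes 1 of 330 against 16.0 (exact test, adjusted p = 7.92e-07). Keratin genes had 10 of 53 against 14.7 (exact test, adjusted p = 0.123). As for the Hox lists, the exact test treats the genes of a family as independent. Neighbouring members may share their accessibility, so these p-values are likely too small.

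In the main catalogue the Hoxa cluster (chromosome 6, 52155590 to 52260880) had 2 of 11, Hoxa1 and Hoxa5, the Hoxb cluster 1 of 10, Hoxb9, and the Hoxc and Hoxd clusters 0 of 9 each. Replicate 2 listed 5 in Hoxa, 3 in Hoxb (Hoxb9 not among them), 1 in Hoxc and 0 in Hoxd, and replicate 1 listed 1 in Hoxa and 0 elsewhere. The replicated list had 7 in Hoxa, 7 in Hoxb, 4 in Hoxc and 7 in Hoxd, among the last Hoxd1, Hoxd3, Hoxd8 and Hoxd13.

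Among distal regions listed in 1 replicate only, GATA sites were in 4.50% of summit windows of replicate 1 and 0.741% of replicate 2, FOXA sites in 6.28% and 3.13%, AP-1 sites in 9.74% and 9.64%, and CTCF sites in 1.47% and 3.79%. The regions of replicate 1 only were at promoters in 5.53% of cases and those of replicate 2 only in 13.3%.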
